A study of Homo sapiens with 6 samples.

How the data were processed

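RNA-seq was done on 6 libraries of HUVECs kept for 24 h in alginate gels, 3 with LDAP and 3 with RGDS. Total RNA was extracted with RNeasy columns and DNase, and libraries were made with the SMART-Seq v4 kit. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, trimmed with cutadapt 1.11, counted with HTSeq and analysed with DESeq2. The aligner, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of paralogs are uncertain. The notes name the genome builds hg19 and mm10 without a role, so no coordinates are printed. The reference used here, GENCODE v29 on GRCh38, served only for gene classes, lengths, GC content and host genes.

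The authors deposited 1 table with 25385 rows. Its sample columns hold log2 values that the authors made by dividing each gene's count by a size factor of its library, adding 1 and taking the binary logarithm. This unit was worked out from the values and is not stated with the table. Raising 2 to each value and subtracting 1 gave whole multiples of a step per library, within 0.05 reads for values under 1000 reads, so whole reads could be recovered. The size factors were within 0.01% of median-of-ratios factors. The authors' deposited table also holds a log2 fold change, a p-value and a Benjamini-Hochberg adjusted p-value for each gene.

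Totals ran from 36088026 to 40173703 reads, a ratio of 1.11, and 17939 to 18609 genes had a read in a library. A gene with 0 reads in a library is compatible with up to 3 counts, or 0.0747 to 0.0831 CPM (reads scaled to the library total), for counting error only. Left out were 110 rows of sex-linked genes, since the cells come from donors, and 16 repeated rows. Names turned into dates (28 rows) were never named, and 0 rows were mitochondrially encoded genes.

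Genes with a mean normalised count of at least 10 were tested with limma-trend (limma 3.58.1 in R 4.3.3) on the deposited log2 values, LDAP minus RGDS, 2-sided, with Benjamini-Hochberg adjustment at 0.05. The plan fixed before the data were examined put this test in place for normalised values. It named a count test for tables of whole-number counts; since whole reads could be recovered, limma-voom on them was run as an alternative. With 3 libraries against 3 an exact permutation test cannot go below 0.1, so none is given for a gene or list; the number of calls was also counted over the 10 splits of the libraries into 3 and 3. Fold means 2 to the power of the difference in mean log2 values.

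Before the data were examined, 49 gene lists and a panel of 20 genes were fixed. Lists with at least 5 tested genes were tested with camera, with a preset correlation between genes of 0.01, which compares a list with all other genes. Beside it stand camera with the correlation estimated for each list and fry, which asks whether a list's genes move on balance and does not compare them with others. Benjamini-Hochberg adjustment ran over the 47 lists tested. Counts of list members adjusted over all tested genes and adjusted over the list alone were identical except where both are given.

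Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose mean was at least 50, leaving out pseudogenes, small RNAs and clone-based names. It also took up to 3 called members of each list by smallest p, the panel, and the 3 called genes of highest mean in each direction. Some genes that the rule took are not named in the text.

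The alternatives were TMM, upper quartile and library-size scaling, limma-voom, no filter, a filter of 50 reads in 3 libraries, a minimum mean of 50, robust variances in limma, pseudocounts of 0.1, 0.5, 5 and 10, thresholds of 0.01 and 0.1, a log2 fold limit of 1, each library left out in turn, the replicate number as a block, and removal of trends on GC content and length (known for 13472 tested genes, 93.2%). The planned tests with other count packages were not run, and the planned size-factor scaling is the deposited one.

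On simulated counts with 14376 tested genes, the same steps recovered 52%, 78%, 94% and 100% of 50 genes each changed by 1.2, 1.5, 2 and 4-fold. They made 172 calls, 10 of them false, and called 0 of 40 lists without a change. The simulated genes were drawn independently, and a far smaller share of them changed than the 59.5% called in the data. The shares recovered and the absence of false lists therefore do not carry over to the real libraries. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.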

Results

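RNA was sequenced from human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical vein, that had spent 24 h inside alginate hydrogels. Alginate is a seaweed polysaccharide that offers cells few adhesion sites of its own, and a peptide coupled to it supplies them. In 3 libraries the gel carried LDAP, a peptide derived from laminin and described by the submitters as angiogenic. In the other 3 it carried RGDS, a short peptide with the Arg-Gly-Asp motif through which fibronectin and similar proteins bind integrins. Both gels held 1% alginate, 0.125 mmol of peptide per g and the same density of cells, at passage 2 to 3. The design asks how gene expression differs between cells held by the laminin-derived peptide and cells held by RGDS. A gel without peptide was not analysed here, so every difference is one of LDAP relative to RGDS.

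The LDAP libraries held 37369323, 38821912 and 38772771 counted reads (replicates 1, 2 and 3) and the RGDS libraries 36088026, 38766746 and 40173703 reads (replicates 2, 3 and 4). Of 25259 genes analysed, 14460 passed the expression filter and were tested. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

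The peptide was accompanied by a broad difference in gene expression. LDAP cells held higher transcript levels of inflammatory adhesion molecules and chemokines, interferon-response genes, the Notch ligand DLL4 and components of the extracellular matrix. The venous and lymphatic lists were higher too (camera adjusted p = 0.00419 and 0.0199). The arterial list, with 9 of 15 genes higher and 4 lower, just missed the threshold (camera adjusted p = 0.0593). Of the gene lists called here with a preset correlation, 0 passed with an estimated correlation (lowest adjusted p = 0.293). LDAP cells held lower levels of immediate early genes, YAP-TAZ targets, enzymes of cholesterol synthesis and DNA replication genes. The same limit holds for these lists (adjusted p = 0.381 to 0.444 with an estimated correlation). Angiogenic genes went both ways, with APLN, PGF and ANGPT2 lower and the receptors FLT1, TEK and FLT4 higher. Of 26 angiogenic factors and receptors 11 were higher and 12 lower, and that list was not called (camera adjusted p = 0.601). In limma-trend with Benjamini-Hochberg adjustment, 4467 genes were higher and 4143 lower in LDAP at an adjusted p of 0.05, together 59.5% of the genes tested. Most of these differences were small: the median fold was 1.29, 68.1% lay under 1.5-fold, and 650 higher and 734 lower genes passed 2-fold (1 on the log2 scale). The 3 values of LDAP lay all above or all below those of RGDS for 9484 genes (65.6%, where chance gives 10%).

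Component 1 of a principal component analysis held 79.8% of the variance and parted the peptides, with LDAP libraries at 37.23 or more and RGDS libraries at -34.51 or less. Pearson correlations of log2 values across genes were 0.9947 to 0.9958 within a group and 0.9702 to 0.9751 between groups (genes are not independent replicates). No pair of libraries agreed within the sampling noise of independent reads. The chi-square of their reads per degree of freedom was 3.31 to 7.98 within a group and 89.89 to 112.36 between groups.

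**Figure D1:**
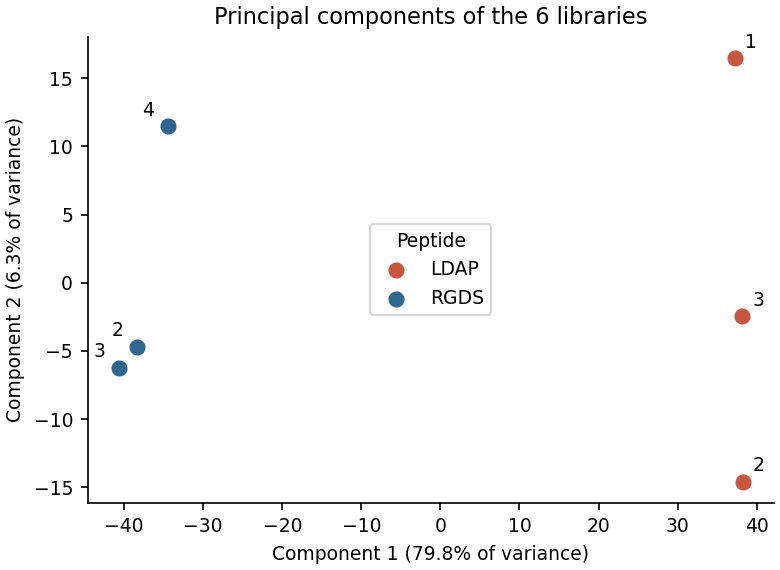
Principal components of log2 normalised read counts over the 14460 tested genes, with component 1 (79.8% of variance) on the x axis and component 2 (6.3%) on the y axis. Each point is a library, coloured by peptide and numbered by replicate, and the 3 LDAP libraries lie at 37.23 or more on component 1 while the 3 RGDS libraries lie at -34.51 or less.

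The 10 largest rises in LDAP were taken among called genes with a mean of at least 50 normalised read counts. CCL1, a chemokine, (Entrez gene 6346 in the files) stood at 165 ± 3.26 normalised read counts (SD, n = 3) in LDAP and 0.669 ± 0.581 in RGDS, where only 2 reads were seen in all. The ratio was 252 with a 95% counting interval of 69.4 to 2090. Such intervals cover counting error only, since reads amplified by PCR are not independent molecules. IL33 (Entrez 90865), a nuclear cytokine, was 40.6-fold higher (4869 ± 441 against 121 ± 28.1, adjusted p = 2.78e-13). VCAM1 (Entrez 7412), an adhesion molecule for leukocytes, was 24.9-fold higher (1644 ± 167 against 69.6 ± 30.1, adjusted p = 7.2e-10). ACKR1, an atypical chemokine receptor of venules, rose 58.1-fold from 2.23 ± 2.42 to 153 ± 46.6. UBD, a ubiquitin-like modifier induced by cytokines, rose 48.0-fold, and EBI3, a cytokine subunit, 25.8-fold. The other 4 were IGFBP5 (22.2-fold), P2RY6 (20.9-fold), CLEC10A, a lectin best known from macrophages and dendritic cells, (19.7-fold) and SLCO2A1 (17.5-fold). Except for IL33 and VCAM1, with 371 and 211, these genes had 2 to 40 reads in all in RGDS, so their folds rest on few reads. Leaving out 1 library moved 3 of them by over 1.5 times. The log2 fold change of ACKR1, 5.86 over all libraries, was 5.18 without RGDS replicate 2 and 6.45 without RGDS replicate 3. That of IGFBP5 went from 4.47 to 5.07 without RGDS replicate 3, and that of P2RY6 from 4.38 to 3.48 without RGDS replicate 3 and to 5.07 without RGDS replicate 4.

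The 10 largest falls were taken in the same way. NPTX1 (Entrez 4884), a secreted pentraxin best known from neurons, was 13.4-fold lower (126 ± 32.3 against 1671 ± 188 normalised read counts, SD, n = 3, adjusted p = 3e-11). ARC (Entrez 23237), an immediate early gene, was 11.4-fold lower (295 ± 48.2 against 3376 ± 523, adjusted p = 9.77e-12). FOS and EGR1, both immediate early transcription factors, were 6.43-fold and 5.86-fold lower. APLN (Entrez 8862), which encodes the angiogenic peptide apelin, was 5.52-fold lower (2412 ± 202 against 13286 ± 536, adjusted p = 1.24e-13). The remaining 5 were RGS16 (10.4-fold), RASD1 (8.34-fold), NEFM (7.63-fold), IFNE (7.31-fold) and ADAM32 (5.95-fold).

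Of the most abundant called genes, FN1, which encodes fibronectin, was 2.16-fold higher in LDAP (337700 ± 25240 against 156170 ± 6174), the basement membrane proteoglycan HSPG2 1.45-fold higher and the ferritin light chain FTL 1.37-fold higher. THBS1, an inhibitor of angiogenesis, was 1.80-fold lower (162890 ± 8668 against 293040 ± 7612), the collagenase MMP1 1.79-fold lower and ACTB 1.14-fold lower.

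**Figure D2:**
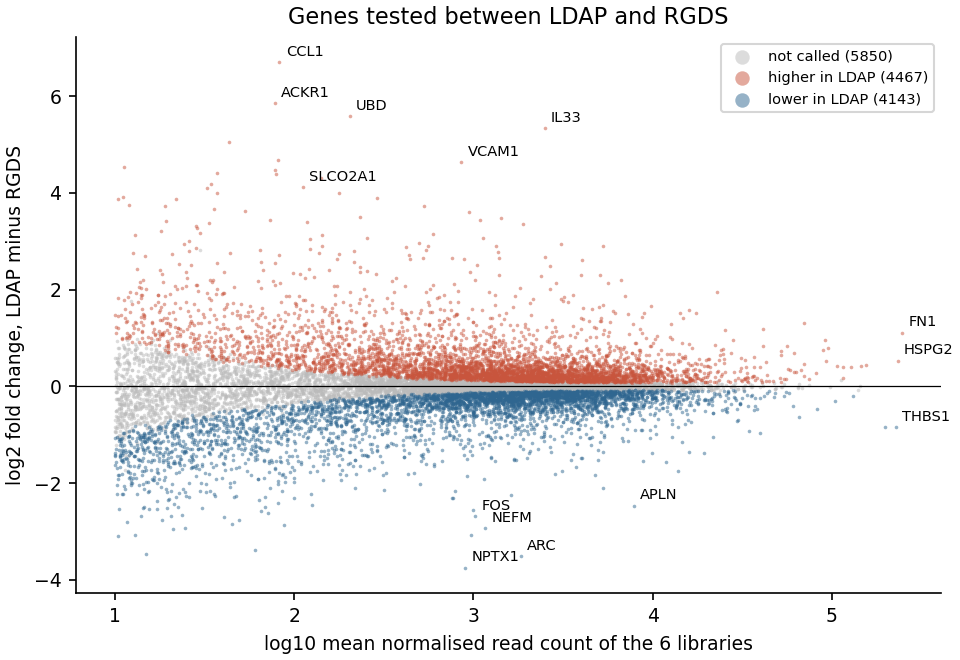
Every tested gene by its log10 mean normalised read count (x axis) and its log2 fold change of LDAP minus RGDS (y axis), with 4467 genes called higher and 4143 called lower at an adjusted p of 0.05 in limma-trend. Each point is a gene; the labelled genes are among the largest and most abundant changes, from CCL1 and IL33 at the top to NPTX1 at the bottom.

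The list of endothelial activation and NF-kB genes rose as a group, with 21 of its 27 tested genes higher in LDAP and 3 lower (22 and 3 adjusted over the list alone), a median log2 fold change of 1.00 and a camera adjusted p of 1.57e-05. That call was lost in camera with an estimated correlation (adjusted p = 0.444), a form with few degrees of freedom in these libraries. CCL2, a chemokine for monocytes, was 4.57-fold higher (10881 ± 855 against 2381 ± 156 normalised read counts, SD, n = 3), BIRC3, an apoptosis inhibitor under NF-kB control, 4.25-fold higher, and NFKBIA, the NF-kB inhibitor, 2.88-fold higher. The interferon response list also rose, with 26 of 29 genes higher and 1 lower and a median of 1.37. Its camera adjusted p was 0.000202 (adjusted p = 0.724 with an estimated correlation). The correlation estimated for this list was 0.876, far above the preset 0.01, so the preset p-value is too small if that estimate holds. MX2, an antiviral GTPase named after its values were seen, had 0 reads in RGDS and was at least 61.4-fold higher in LDAP, taking its 178 LDAP reads as counted, against a floor of 3 reads over the group. With MX2 at that bound the median was also 1.37. IFIH1, a sensor of viral RNA, was 3.71-fold higher, HERC5 3.44-fold and IFIT2 2.88-fold. LDAP replicate 2 stood highest in this list: the median difference from the RGDS mean was 1.89 in it, 0.67 in replicate 1 and 1.01 in replicate 3. Without LDAP replicate 2 the list median was 0.87, and 25 of the 26 genes were still called higher. Of 7 tested leukocyte markers, 3 were higher beside these lists and 1 lower (camera adjusted p = 0.48).

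Genes of angiogenic sprouting went in both directions. In the tip cell list, which covers genes of the leading cells of a sprout, 7 of 19 genes were higher and 10 lower (camera adjusted p = 0.44): APLN was lower, while DLL4, the Notch ligand of tip cells, rose 4.04-fold and FLT4, a receptor for VEGF-C, 3.10-fold. Notch pathway and stalk cell genes rose as a list, 13 of 18 higher and 2 lower with a median of 0.33 (camera adjusted p = 0.00855; adjusted p = 0.444 with an estimated correlation). Besides DLL4, it held FLT1, a decoy receptor for VEGF, 2.02-fold higher, and the angiopoietin receptor TEK, 1.97-fold higher. In the VEGF pathway list 7 of 21 genes were higher and 11 lower (camera adjusted p = 0.427), with PGF, a ligand of FLT1, 2.61-fold lower and PTGS2, the inducible cyclooxygenase, 2.19-fold lower. Angiogenic factors and receptors split into 11 higher and 12 lower of 26 (camera adjusted p = 0.601); the matricellular genes CTGF and CYR61 were 3.37-fold and 2.95-fold lower. Of 15 anti-angiogenic genes, 8 were higher and 3 lower (camera adjusted p = 0.242): SPARC was 1.73-fold higher and the chemokine CXCL10 18.2-fold higher (66.1 ± 21.0 against 2.60 ± 0.442), but THBS1 was lower.

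Markers of vessel type were higher more often than lower. Among 15 arterial genes 9 were higher and 4 lower (5 lower when adjusted over the list alone), with a median of 1.02. The list just missed the threshold (camera adjusted p = 0.0593) and passed it without LDAP replicate 3 (0.0393) or without RGDS replicate 3 (0.0292); over the other settings with the preset correlation its adjusted p ran from 0.0134 without a filter to 0.131. SEMA3G was 12.2-fold higher (1744 ± 99.6 against 142 ± 1.99) and EFNB2, the arterial ephrin, 3.64-fold higher. The venous list rose too, with 6 of 9 genes higher and 0 lower and a median of 0.98 (camera adjusted p = 0.00419, or 0.384 with an estimated correlation). It included EPHB4, the receptor of EFNB2, at 1.82-fold. Its higher genes also held TEK, shared with the Notch list, and FLT4, shared with the lymphatic list, so these lists are not independent. Lymphatic endothelial genes rose, 6 of 8 higher and 1 lower with a median of 0.85 (camera adjusted p = 0.0199; adjusted p = 0.444 with an estimated correlation); the hyaluronan receptor LYVE1 was 3.02-fold and the transcription factor PROX1 1.77-fold higher. Of 27 endothelial identity genes, 14 were higher and 8 lower (camera adjusted p = 0.281): PLVAP, a protein of fenestral diaphragms, was 7.73-fold higher and THBD, thrombomodulin, 2.34-fold lower.

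Matrix genes were higher in LDAP, and with them fibroblast markers, 6 of 9 higher and 2 lower with a median of 0.61 (camera adjusted p = 0.171). In the interstitial matrix list 21 of 28 genes were higher and 2 lower, with a median of 0.41 (camera adjusted p = 0.000131; adjusted p = 0.384 with an estimated correlation); besides FN1, the proteoglycan gene BGN was 2.28-fold and the collagen gene COL1A2 3.70-fold higher. The list of laminins and basement membrane genes rose, 13 of 21 higher and 4 lower with a median of 0.41 (camera adjusted p = 0.014; adjusted p = 0.724 with an estimated correlation). LAMB3, a laminin chain, was 7.44-fold higher (9369 ± 751 against 1258 ± 99.7), and NID1, which links laminin to collagen IV, 2.85-fold higher. Syndecans and heparan sulfate enzymes rose, 13 of 22 higher and 4 lower with a median of 0.22 (camera adjusted p = 0.0274; adjusted p = 0.519 with an estimated correlation), with the cell surface proteoglycan SDC1 at 7.45-fold and the extracellular sulfatases SULF1 and SULF2 at 4.41-fold and 1.53-fold. Matrix proteases and their inhibitors rose as well, 17 of 27 higher and 4 lower (19 and 4 adjusted over the list alone) with a median of 0.23 (camera adjusted p = 0.0146; adjusted p = 0.444 with an estimated correlation). ADAMTS4 and CTSS were 2.18-fold and 2.62-fold higher, and MMP10 3.15-fold lower.

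Integrins themselves were mixed, with 10 of 18 higher and 5 lower (camera adjusted p = 0.411): ITGA1, a collagen receptor chain, was 7.35-fold higher (742 ± 84.1 against 99.7 ± 3.40), and ITGA11, another collagen receptor chain, 2.51-fold lower. In the focal adhesion list 9 of 27 genes were higher and 14 lower (camera adjusted p = 0.304), with FERMT3, an integrin activator, 1.65-fold lower, TNS1 1.73-fold higher and LIMS1 1.69-fold higher. Junction genes rose, 11 of 20 higher and 2 lower with a median of 0.17 (camera adjusted p = 0.0414; adjusted p = 0.567 with an estimated correlation). This call was lost without LDAP replicate 1 (adjusted p = 0.0543), without RGDS replicate 2 (0.0648) and after removal of trends on GC content and length (0.161), and its lowest adjusted p with the preset correlation was 0.00793, without a filter. The gap junction gene GJA4 was 11.4-fold higher (425 ± 34.5 against 38.6 ± 16.4), F11R 1.59-fold and JUP 1.49-fold.

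Of 7 lists of genes that respond to mechanical and growth signals, those of immediate early genes and YAP-TAZ targets fell and the other 5 did not pass. Immediate early genes fell as a list, with 17 of 25 lower and 4 higher and a median of -0.91 (camera adjusted p = 0.000139; adjusted p = 0.444 with an estimated correlation). Nuclear-retained RNAs, a sign of RNA composition, fell beside these lists, with 12 of 12 lower and a median of -0.83 (adjusted p = 0.492 with an estimated correlation). YAP-TAZ targets, which respond to cell spreading and tension, fell, with 14 of 23 lower and 4 higher (14 and 5 adjusted over the list alone) and a median of -0.32 (camera adjusted p = 0.00419; adjusted p = 0.384 with an estimated correlation). Its leading members were CTGF (6336 ± 216 against 21381 ± 581), CYR61 (6007 ± 209 against 17689 ± 273) and ANKRD1, 2.28-fold lower. Targets of MRTF and SRF, regulators of actin genes, did not pass as a list, with 4 of 23 higher and 10 lower (camera adjusted p = 0.346): FHL2 was 1.38-fold lower, MYH10 2.16-fold and MYL9 1.46-fold higher. Flow-responsive KLF2 and KLF4 genes split into 6 higher and 7 lower of 15 (camera adjusted p = 0.859), and their median of -0.24 and mean of 0.30 differed in sign; the water channel AQP1 was 10.2-fold higher. TGF-beta response genes split into 8 higher and 7 lower of 21 (9 and 7 adjusted over the list alone, camera adjusted p = 0.681), or 7 higher and 9 lower with scaling by library size alone, with ID2 3.76-fold lower. In the endothelial-to-mesenchymal list 6 of 15 were higher and 3 lower (camera adjusted p = 0.904), with a median of -0.07 and a mean of 0.04; SNAI1 was 1.59-fold lower and MMP2 1.26-fold higher. In the Wnt list 5 of 15 were higher and 3 lower (camera adjusted p = 0.681), with a median of 0.05 and a mean of -0.06; CTNNB1 was 1.59-fold higher, FZD6 1.29-fold higher and the Wnt inhibitor DKK1 3.04-fold lower.

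**Figure D3:**
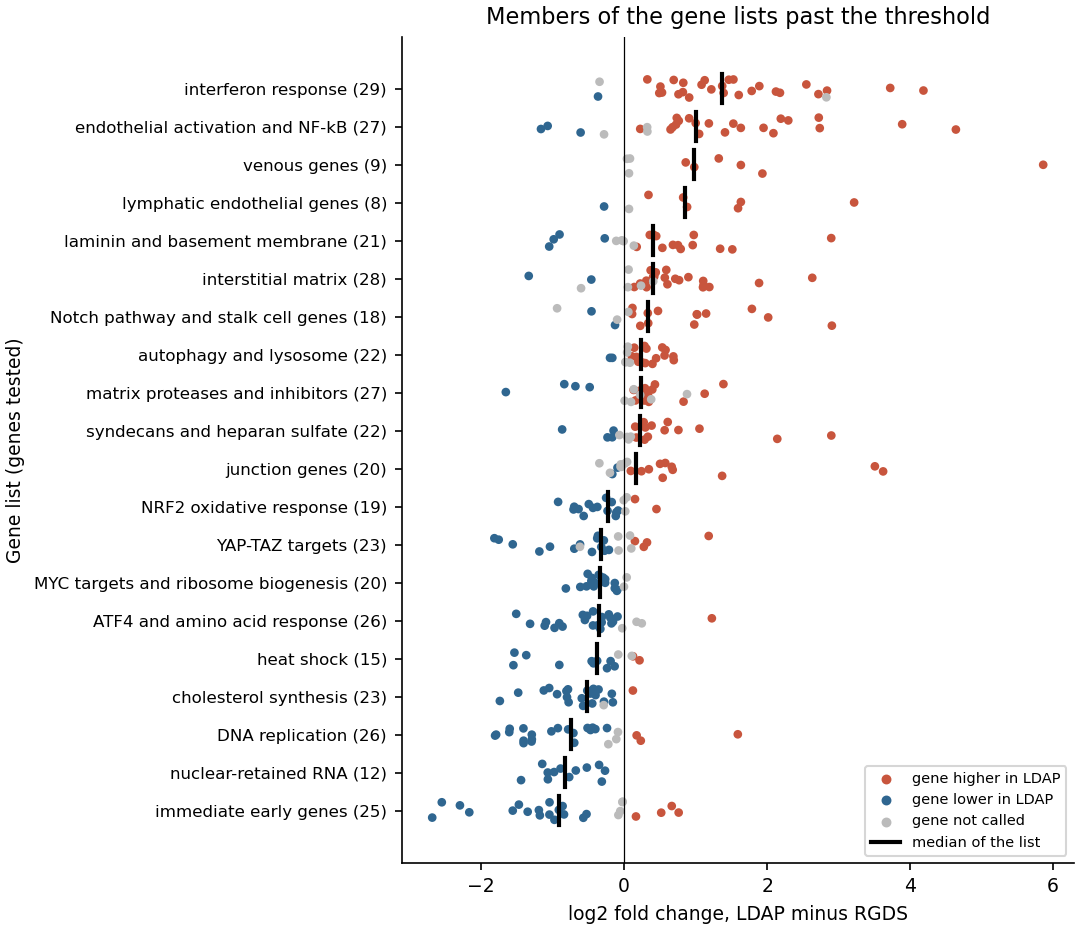
Log2 fold change of LDAP minus RGDS (x axis) for the tested members of the 20 gene lists past the camera threshold at a preset correlation, 1 list per line. Points are genes coloured by their own call and black bars are list medians, which run from 1.37 for the interferon response to -0.91 for immediate early genes; with an estimated correlation 0 of the 20 lists passed.

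Several metabolic and stress lists fell in LDAP, beside a fall of nuclear-retained RNAs (12 of 12 lower, camera adjusted p = 7.58e-05; adjusted p = 0.492 with an estimated correlation). Cholesterol synthesis genes fell, with 21 of 23 lower and 1 higher and a median of -0.52 (camera adjusted p = 8e-07; adjusted p = 0.444 with an estimated correlation). SQLE, the squalene epoxidase, was 2.18-fold lower (1549 ± 52.7 against 3382 ± 246). The ATF4 and amino acid response list fell, 22 of 26 lower and 1 higher (22 and 2 adjusted over the list alone) with a median of -0.35 (camera adjusted p = 1.57e-05; adjusted p = 0.293 with an estimated correlation); PHGDH, of serine synthesis, was 2.85-fold and the amino acid transporter SLC7A5 2.13-fold lower, while DDIT4, an mTORC1 inhibitor, was 2.34-fold higher. MYC targets and ribosome biogenesis genes fell, 18 of 20 lower and 0 higher with a median of -0.34 (camera adjusted p = 1.85e-05; adjusted p = 0.384 with an estimated correlation), led by ODC1 (1.76-fold), NOP56 (1.53-fold) and MYC itself (1.44-fold). NRF2 targets fell, 14 of 19 lower and 2 higher with a median of -0.23 (camera adjusted p = 0.00419; adjusted p = 0.567 with an estimated correlation), TXNRD1 by 1.90-fold and GCLM by 1.63-fold. Heat shock genes fell, 11 of 15 lower and 2 higher with a median of -0.38 (camera adjusted p = 0.00586; adjusted p = 0.492 with an estimated correlation); the small chaperone CRYAB was 2.90-fold, BAG3 1.37-fold and HSPA1B 2.93-fold lower, although HSPA1B and HSPA1A have near-identical sequences, so its reads are uncertain. Autophagy and lysosome genes rose, 15 of 22 higher and 2 lower with a median of 0.23 (camera adjusted p = 0.0012; adjusted p = 0.444 with an estimated correlation), with the lysosomal enzymes HEXA and CTSD at 1.62-fold and 1.61-fold.

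Other metabolic lists did not pass. Hypoxia genes were higher in 13 and lower in 10 of 27 (11 lower when adjusted over the list alone, camera adjusted p = 0.768), with the glucose transporters SLC2A1 2.11-fold lower and SLC2A3 2.06-fold higher. With scaling by library size alone 9 hypoxia genes were higher and 11 lower, 6 glycolysis genes higher and 6 lower, and 7 ER stress genes higher and 8 lower. Among 19 glycolysis genes 7 were higher and 4 lower (camera adjusted p = 0.859), with a median of 0.03 and a mean of -0.01; PFKP was 1.35-fold lower and PFKM 1.27-fold higher. Of 25 oxidative phosphorylation genes, 8 were higher and 2 lower (camera adjusted p = 0.391), led by UQCRC2, NDUFA4 and NDUFA9 at 1.17-fold, 1.18-fold and 1.16-fold; with scaling by library size alone 4 were higher and 3 lower. Genes of ER stress and unfolded proteins were 10 higher and 7 lower of 22 (8 lower when adjusted over the list alone, camera adjusted p = 0.833), with the chaperone CALR 1.56-fold, DNAJC3 1.49-fold and SEL1L 1.31-fold higher. Ribosomal protein genes were 16 higher and 2 lower of 37 (15 and 2 adjusted over the list alone, camera adjusted p = 0.134), led by RPL15, RPL10 and RPL19 at log2 fold changes of 0.26, 0.18 and 0.17. With scaling by library size alone 6 were higher and 3 lower, and the list passed without a filter (adjusted p = 0.0467) and after removal of trends on GC content and length (0.00147). Processed pseudogenes share their sequence, so these counts are uncertain.

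Replication genes fell in LDAP, beside the nuclear-retained RNAs (12 of 12 lower, median -0.83, adjusted p = 0.492 with an estimated correlation), while mitotic genes were mixed. In the DNA replication list 20 of 26 genes were lower and 3 higher (22 and 3 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.14e-05; adjusted p = 0.381 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was 3.50-fold lower (190 ± 7.91 against 668 ± 50.4) and the helicase subunit MCM5 2.65-fold lower, but RFC3, of the clamp loader, was 3.01-fold higher. Among 25 mitosis genes 9 were higher and 12 lower (10 and 12 adjusted over the list alone, camera adjusted p = 0.411): MKI67, a marker of cycling cells, was 3.14-fold lower, whereas the kinetochore genes CENPE and TTK were 2.23-fold and 2.92-fold higher. Replication-dependent histone genes were lower in 3 of 8 (2 when adjusted over the list alone, camera adjusted p = 0.308), namely HIST1H1E (2.95-fold), HIST1H2BD (1.45-fold) and HIST2H2BE (1.41-fold). HIST1H1E had 3, 9 and 5 reads in the LDAP libraries against 17, 14 and 24 in RGDS, so its fold rests on few reads. HIST1H2BD lost its call without each of LDAP replicates 1, 2 and 3 and RGDS replicates 2 and 3 (adjusted p 0.0503 to 0.208). The histone copies share sequence. Cell cycle brakes were higher in 7 and lower in 2 of 13 (8 and 2 adjusted over the list alone, camera adjusted p = 0.166), with CCNG2 1.52-fold higher, RBL2 1.18-fold higher and FOXO1 1.19-fold lower. The p53 targets were higher in 13 and lower in 3 of 23 (camera adjusted p = 0.166), with BTG2, ZMAT3 and DDB2 at 1.70-fold, 1.62-fold and 1.43-fold. Apoptosis genes were 8 higher and 8 lower of 21 (camera adjusted p = 0.833), with BMF 2.08-fold higher and BIRC5 1.85-fold lower; the test was on the lower side although the median was 0.02 and the mean 0.08, and with scaling by library size alone 5 were higher and 10 lower.

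The fixed panel of 20 receptor and endothelial genes held 12 genes higher and 6 lower in LDAP, with the same counts adjusted over the list alone. Of the integrin chains, ITGAV, which pairs with ITGB3 to bind Arg-Gly-Asp, was 1.83-fold higher (20609 ± 184 against 11292 ± 395 normalised read counts, SD, n = 3, adjusted p = 4.74e-11). ITGA5, the fibronectin receptor chain, was 1.22-fold, ITGA3, a laminin receptor chain, 1.16-fold, ITGB3 1.13-fold and ITGB1 1.10-fold higher. ITGA6, another laminin receptor chain, differed by -0.09 on the log2 scale (SE 0.04, adjusted p = 0.0915), and was called lower without LDAP replicate 1 (adjusted p = 0.0347) and without RGDS replicate 3 (0.0109). SDC4, a syndecan of focal adhesions, was 1.48-fold higher and DAG1, the laminin receptor dystroglycan, 1.12-fold lower. Apart from DLL4, FLT1 and TEK, the junction protein PECAM1 was 1.42-fold, VWF 1.37-fold and the protease MMP14 1.12-fold higher. CXCR4, a chemokine receptor of tip cells, was 3.52-fold lower (1261 ± 118 against 4454 ± 528), ANGPT2 2.57-fold (2965 ± 397 against 7594 ± 324), VEGFA 1.43-fold, NOS3 1.18-fold and KDR, the main VEGF receptor, 1.16-fold. The cadherin CDH5 differed by 0.04 (SE 0.03, adjusted p = 0.309).

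**Figure D4:**
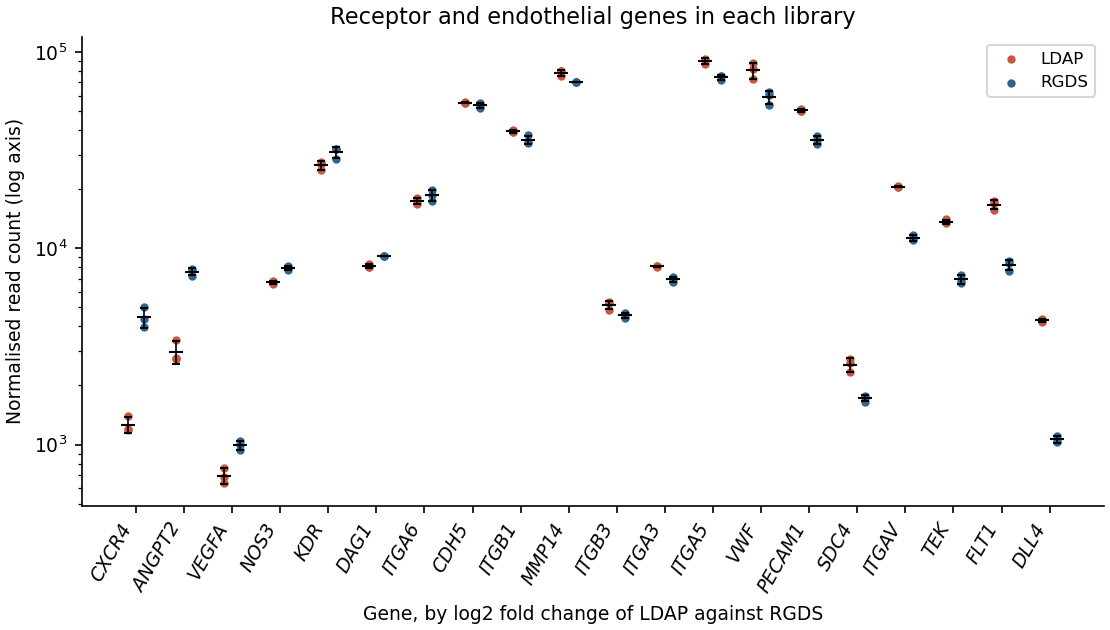
Normalised read counts (y axis, log scale) of the 20 panel genes (x axis, ordered by log2 fold change) in each of the 3 LDAP and 3 RGDS libraries. Points are libraries, and black bars are the group mean ± SD; the groups lie farthest apart for DLL4 (4.04-fold higher in LDAP) and CXCR4 (3.52-fold lower).

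Lists for RNA quality and for other cell types were read beside these results. Nuclear-retained RNAs fell as a list, with 12 of 12 genes lower and a median of -0.83 (camera adjusted p = 7.58e-05; adjusted p = 0.492 with an estimated correlation); the splicing-related genes PNN, CLK1 and LUC7L3 were 1.85-fold, 1.97-fold and 1.70-fold lower. Smooth muscle and pericyte markers were 3 higher and 2 lower of 10 (camera adjusted p = 0.681), with NOTCH3 3.45-fold and ACTA2 1.60-fold higher and SMTN 1.45-fold lower. Fibroblast markers were 6 higher and 2 lower of 9 (camera adjusted p = 0.171), with COL1A2 again higher, S100A4 2.15-fold and FAP 3.06-fold higher. Leukocyte markers were 3 higher and 1 lower of 7 tested (camera adjusted p = 0.48), with LAPTM5 1.65-fold, CD68 1.39-fold and CD74 2.96-fold higher. Epithelial markers were 2 higher and 3 lower of 8 (camera adjusted p = 0.665), with a median of 0.05 and a mean of -0.23; KRT19 was 1.25-fold higher, KRT18 1.28-fold and CLDN3 2.26-fold lower. Erythroid and platelet markers held 16 reads in LDAP and 37 in RGDS over 11 genes and were not tested. The list of mitochondrially encoded genes had 0 of its genes in the table.

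Set against the authors' deposited table, 7424 genes were called both here and there, all 7424 in the same direction. Another 1186 genes were called here and not there, and 3 tested genes there and not here. The authors' deposited table held 7561 calls at an adjusted p of 0.05, 3952 higher and 3609 lower in LDAP. Log2 fold changes here and in the authors' deposited table correlated across the tested genes with a Pearson's r of 0.973 and a Spearman's rho of 0.997 (genes are not independent replicates). The largest folds differed more: the authors' deposited log2 fold changes of the 10 largest rises and 10 largest falls all lay closer to 0 than those computed here, at 4.34 against 6.71 for CCL1 and 1.17 against 4.38 for P2RY6. The 6.71 of CCL1 depends on the 1 added before the logarithm, since RGDS held 2 reads of it. Its ratio of reads between the groups was 252.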

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

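The alternatives were planned before the data were examined, and 153 of the 157 genes taken by the naming rule kept their direction and their side of the 0.05 threshold under the scaling, tool, filter, pseudocount, replicate and trend alternatives; the other thresholds were applied only to counts. The exceptions were ITGA6, which was called lower in 5 settings, and HIST1H2BD, which lost its call in some; HIST1H1E and HIST2H2BE lost theirs only with the replicate block. Leaving out each library gave 3967 to 4339 genes higher and 3677 to 3991 lower in LDAP, 10 to 12 lists higher and 9 lower. Scaling by library size alone gave 3761 higher and 4904 lower, so the balance of the calls (43.4% higher, against 51.9%) depends on scaling; it shifted the median of all genes to -0.042. TMM gave 4599 and 4027, upper quartile scaling 4389 and 4198, limma-voom 4467 and 4137, no filter 4441 and 4387, and the replicate block 4399 and 3977. Removal of trends on GC content and length gave 4283 and 4167. A log2 fold limit of 1 left 650 higher and 734 lower, because it adds a criterion. Component 1 held 86.6% of the variance over the 500 most variable genes.

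Of the 20 called lists, 19 kept their call under every alternative that used camera with the preset correlation; the junction list lost it in 5, the replicate block among them. With an estimated correlation 0 lists were higher and 0 lower, the lowest adjusted p being 0.293, while fry called 23 higher and 15 lower. That lowest value belonged to the ATF4 list, whose estimated correlation of 0.002 lay below the preset 0.01. Correlation between its genes therefore did not lose its call. That cannot be said of the other called lists, whose estimated correlations lay above the preset. They reached 0.435 for cholesterol synthesis, 0.443 for laminins and basement membrane, 0.697 for nuclear-retained RNAs and 0.876 for the interferon response. For such lists the preset p-values are too small if the estimates hold. The estimated form has few degrees of freedom here, so it cannot tell which lists lack a shift. The flow-responsive KLF2 and KLF4 list, lower in camera without a call, was higher in fry with an adjusted p of 0.008; the cause was not tested. In simulated data 52% of 1.2-fold changes were recovered, so small changes can be missed. The share missed in the real data is not known, since far fewer genes changed in the simulation. The planned tests with other count packages were not run.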

Other observations

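The tests of the amount of genomic DNA, of leukocytes, of stress during recovery and of ERK signalling were chosen after the results were seen. The same holds for the 7 gene lists of the next paragraph and the genes named from them. Lists picked with the values known can pass for that reason alone. Their p-values, adjusted over these 7 lists only, are therefore descriptions.

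Metallothioneins, small metal-binding proteins, rose in LDAP, with 8 of 9 higher and a median log2 fold change of 2.78 (camera adjusted p = 2.22e-05; adjusted p = 0.0677 with an estimated correlation). MT1G was 13.3-fold and MT1X 6.88-fold higher, although these genes share sequence. MHC class I antigen presentation genes rose, 19 of 20 higher and 0 lower with a median of 0.65 (camera adjusted p = 9.72e-08; adjusted p = 0.178 with an estimated correlation), among them B2M at 1.78-fold and TAP1 at 1.76-fold. All 5 guanylate-binding proteins tested were higher (camera adjusted p = 0.00641; adjusted p = 0.2 with an estimated correlation). ERK target and feedback genes fell, 14 of 18 lower and 3 higher with a median of -0.60 (camera adjusted p = 5.91e-05; adjusted p = 0.0741 with an estimated correlation): SPRY2, a feedback inhibitor, was 2.40-fold lower and DUSP6, an ERK phosphatase, 1.30-fold higher. Ephrins and Eph receptors (11 higher and 4 lower of 18, camera adjusted p = 0.0637), semaphorins, plexins and netrin receptors (14 and 9 of 31, 0.242) and neuronal genes (2 and 6 of 14, 0.122) did not pass.

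By gene class, 72 of 88 tested snoRNA genes were lower in LDAP and 0 higher, with a median of -1.24. Of 39 miRNA genes, 25 were lower and 2 higher. These counts cannot tell mature small RNAs from RNA of a host gene that spans them, so they do not measure mature snoRNAs or miRNAs. Long noncoding genes were lower in 170 and higher in 66 of 469, against 3534 lower and 4144 higher of 12674 protein-coding genes. The nuclear noncoding RNAs NEAT1 and MALAT1 were 2.21-fold and 2.10-fold lower.

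Nuclear transcripts and small genes inside introns were lower in LDAP. Genomic DNA in the RGDS libraries met the prediction made for it only in part, since olfactory receptor genes held 1.58 times as many reads, relative to the library totals, in RGDS (95% exact interval 1.31 to 1.89, 309 against 196 reads over 372 genes), but RGDS replicate 4 stood at 1.3 times the LDAP level and fell short of 1.5 times. The amounts, weighed after the results were seen, argue against genomic DNA as the main source of the pattern. At its upper limit it could give 1.1% of the excess of a small gene and 0.0545% of that of the nuclear list. An equal change in the counts of the host genes is argued against by a median difference of -0.89 between small gene and host (95% interval -1.02 to -0.79, 85 of 89 below their host). The 89 small genes share 57 hosts. Host counts do not separate spliced from unspliced RNA, so a change in host transcription stays open. For the nuclear-retained list, GC content and length of the longest annotated transcript are argued against by a median of -0.89 after their trends were removed (-0.83 before). This test did not cover the small genes or the length of unspliced RNA. A difference in how much nuclear or unspliced RNA each library captured, technical or through the peptide, stays open and was not tested.

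Interferon and antigen presentation genes were higher in LDAP. LDAP replicate 2, where they stood highest, is not the sole source, since 96.2% of the interferon genes called higher stayed called without it. Of 15 leukocyte genes, which summed to 1.52 times the RGDS level (1.5 to 1.55), LAPTM5 and CD68 made up most but were already high in RGDS, and the 13 under 10 CPM in RGDS stood at 111% of it (97.2% to 126%, 506 against 458 reads), or at 66.9% (56.7% to 78.8%) without CD74, which endothelium can make under interferon. RNA of leukocytes as the source was weighed by amount, with bounds set after the values were known. The excess was 3040 CPM over 45 interferon and antigen presentation genes called higher. The 13 low genes, CD74 included, came in LDAP to 0.158% of it at their upper limit. The rise of all 15 came to 2.71%, between the bounds for and against. PTPRC, a general leukocyte gene, had 2 reads in LDAP against 10 in RGDS, and TYROBP 0 in both. CLEC10A, outside the 15 genes, went the other way, with 791 reads against 40. The 13 genes argue against a large share of leukocyte RNA, while CLEC10A and the 2.71% leave a smaller share open. A few leukocytes may have induced the interferon and antigen presentation genes in the endothelial cells. A response to the peptide, or to something carried with it, may also account for the pattern. None of these was tested.

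Immediate early and heat shock genes were lower in LDAP. Stress while RGDS cells were recovered before lysis and lower ERK signalling in LDAP cannot be told apart here. The 14 ERK targets outside the immediate early list had a median of -0.6, with 11 lower and 2 higher (78.6% lower), and 77.8% of all 18 ERK genes were lower. The bounds for both tests were set with these values known, so they do not decide. A test on a smaller choice of ERK targets had argued against recovery stress; it was replaced after its result was seen, because it had left out targets that were higher.

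The real split of the 6 libraries gave 8610 calls and the highest of the other splits 0. With 10 splits, of which 1 gave as many, no share under 0.05 is possible.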
